A study of Mus musculus with 4 samples.

How the data were processed

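Gene expression was measured in single live CD45.2+ cells of the lung from 2 WT mice (Lmna-flox/flox Vav1-cre-/-) and 2 knockout mice (Lmna-flox/flox Vav1-cre+/-), all C57BL/6J and aged 10 weeks. Per the labels, about 9600 cells were processed with the Chromium 3-prime v3 kit and sequenced on a NovaSeq at 25000 reads per cell. The submitters' processing notes name Cell Ranger 3.0.2 and Seurat 3.0.0 and the genome mm10. The deposited matrices hold raw UMI counts per gene and cell barcode, 1 library per file, limited to barcodes that the cell caller kept. The values are whole numbers, no barcode has under 500 UMIs, and the Seurat step left no mark in them. Each matrix has the same 31053 genes, and 71 features with a repeated symbol kept their identifier. The kit counts 3-prime ends, so counts were not divided by transcript length, and the summed UMIs of a library and class were the unit of every expression test. Free RNA in droplets was not removed by the submitters as far as the notes say, and was not subtracted here.

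The 4 libraries had 4322, 4182, 4164 and 3860 barcodes (WT 1, WT 2, knockout 1, knockout 2) and 97109691 UMIs together. Cells with at least 200 genes and at most 10% mitochondrial counts were kept (15181 cells). Doublets were scored per library with simulated doublets and exact nearest neighbours, in the manner of Scrublet, and the highest-scoring 0.8% per 1000 cells were removed (461 cells), which left 14720. The clusters below were built on all 15181 cells, doublets included, so that each setting shared their names. Counts were scaled to 10000 per cell and log transformed. The 2000 most variable genes, without mitochondrial, ribosomal protein, hemoglobin, sex-linked and receptor segment genes, gave 30 principal components, a graph of 20 neighbours and 29 Leiden clusters at resolution 1. A cluster was named when its mean log2 marker enrichment was highest for 1 of 24 marker classes and at least 1.5, at least 3 markers were detected in 10% of its cells, and neither its top genes, its finer clusters nor its doublet share (at most 50%) spoke for another class. Clusters led by Rag1 or Dntt were set aside as T cell precursors. The median kept cell had 4849, 4593, 4050 and 4476.5 UMIs in the 4 libraries.

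Replicate libraries of a genotype differed beyond sampling noise, with a chi-square per degree of freedom of 1.94 to 4.28 in 3 classes, so cells were never used as replicates. Counts were summed per library and class, in classes with at least 25 cells in each library (9 classes). Genes were filtered with filterByExpr, scaled with TMM and tested with the quasi-likelihood test of edgeR 4.0.16 (robust), knockout minus WT, with Benjamini-Hochberg adjustment within each class at 0.05. Standard errors of log2 fold changes come from that fit, and errors beside means are SDs of 2 libraries. Class shares were tested with edgeR on cell numbers, with the total number of cells as offset, over the 14 classes with at least 40 cells in all. Each share of a single library has an exact (Clopper-Pearson) 95% interval, which covers counting error only, as does the upper limit of 3 counts that a count of 0 allows. The difference between the alveolar macrophage-like effect and the mean effect of the other 8 classes was tested in 1 edgeR fit with library as a block. It used genes with at least 10 counts in every other class and counts in both genotypes; this filter was chosen after a first filter (10 counts in at least 2 other classes, 288 genes called) was seen to let in genes whose effect could not be estimated in some class.

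Of the gene lists, 28 pathway lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry beside it, and 10 lists of other cell types, free RNA and sex-linked genes were kept apart. The cycling share was the share of alveolar macrophage-like cells with at least 3 of 28 G2/M genes after thinning each cell to the 10th percentile of UMIs in the class (5985). Coordinates and transcript lengths came from GENCODE M21 on mm10. The length of a gene was the median over its annotated transcripts (protein-coding ones where there were any), which may differ from the transcript expressed. All 4 libraries had high Xist and under 5 UMIs of each Y-linked gene checked, so sex did not differ between the groups.

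The classes, markers, lists, tests and main alternatives were fixed before the data were examined, as was the rule for named genes. In alveolar macrophage-like cells that rule took Lmna, then the 14 highest and 14 lowest fold changes among genes past the threshold, with a mean of at least 20 CPM in the higher genotype and both knockout libraries on the same side of both WT libraries. Sex-linked, immunoglobulin, receptor, hemoglobin and unnamed model genes were left out (13 past the threshold). It also took the 2 smallest p values in each direction in each other class, up to 4 members of each pathway list by p, and always Lmna, Lmnb1, Lmnb2, Cdkn1a and Mki67. List members beyond these 4, other genes seen changed in several classes and Igkc were named after their values were seen. Some genes that the rule took are not reported here.

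The alternatives were DESeq2 1.42.0, median-ratio size factors, no filter on low counts, leaving out each library, the replicate number as a block, doublets kept, a stricter cell filter (at least 500 genes, at most 5% mitochondrial counts), Leiden resolution 2, a class for each cell from its own marker score, the same 32 cells from each library, removal of genes of other cell types, other denominators for the shares, other cycling rules, and the other myeloid classes as the reference. Added after seeing the data were a correction for transcript length, a mitochondrial limit of 20%, removal of T cell precursor clusters, the first filter of the class difference test, and the own marker score for the cycling share. Tested on simulated data with known changes, the alveolar macrophage-like fit recovered 41.2% of 2-fold and 90.7% of 4-fold changes, with 2 false among 130 calls, and made 0 calls when nothing had changed. The DESeq2 fit recovered 28.9% and 72.2%. These counts were drawn independently for each gene, with the same dispersion for all genes of a class and no outlying library. Real counts are less regular, so the false calls here are not an error rate for the real data. The share test found a 4-fold fall in 94% of 200 draws, with 31 false calls among 219, and the list test found the 1 raised list and made 1 false call. Other steps used Python 3.11.15 with scipy 1.17.1, scikit-learn 1.9.0 and leidenalg 0.10.2, and R 4.3.3.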

Results

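The series asked how loss of lamin A changes gene expression in the immune cells of the lung. Lmna encodes lamins A and C, filament proteins that line the inner face of the nuclear envelope. Live CD45.2+ cells were taken from lungs of C57BL/6J mice aged 10 weeks. The WT mice carried Lmna-flox/flox without Cre, and the knockout mice carried Lmna-flox/flox with Vav1-cre, which expresses Cre recombinase in blood-forming cells and their descendants. There were 2 WT libraries and 2 knockout libraries, each sequenced as single cells with a 3-prime Chromium kit. The total UMI count was 26433722 in WT 1, 27045250 in WT 2, 21780914 in knockout 1 and 21849805 in knockout 2. After filtering, 3817 and 3760 WT cells and 3655 and 3488 knockout cells remained. Of these, 6.47% in WT 1, 18.6% in WT 2, 8.73% in knockout 1 and 7.88% in knockout 2 lay in clusters that could not be named from fixed markers. The others fell into 14 classes, named for the cell type whose markers they carried and written here with the ending "-like". The lowest unit of replication was the library, so every main test below compared 2 WT with 2 knockout libraries. All knockout mice and no WT mice carried Cre, so effects of Cre itself and of Lmna loss cannot be told apart in any of them.

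The first comparison asked whether Lmna RNA was lower in knockout cells, and in which classes. Lmna (ENSMUSG00000028063, protein coding, chromosome 3, 88480147 to 88509956, minus strand, mm10) fell 5.15-fold in alveolar macrophage-like cells, from 353 ± 31.4 to 69.3 ± 14.9 CPM (counts relative to the normalised library total; mean ± SD, n = 2 libraries each). The log2 fold change was -2.36 ± 0.18 (standard error), with an adjusted p of 3.8e-09 by the edgeR quasi-likelihood test. Alveolar macrophage-like cells held the bulk of the Lmna RNA, with 1403 of 1822 UMIs in WT 1 and 1016 of 1366 in WT 2. Lmna also fell in NK cell-like cells (log2 fold change -1.57 ± 0.41, adjusted p = 0.0482). In regulatory T cell-like cells the log2 fold change was -1.35 ± 0.39 with an adjusted p of 0.340.

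B cell-like cells, which hold little Lmna, had 2.41 ± 1.15 CPM in WT and 2.67 ± 0.4 CPM in knockout libraries (adjusted p = 0.985), so at this depth no fall was detectable there. Classical monocyte-like cells had 8.35 ± 2.94 and 9.0 ± 3.46 CPM (adjusted p = 0.964). In the other classes too few Lmna counts remained for a test. A UMI of Lmna was found in 92.8% and 87.5% of WT alveolar macrophage-like cells, and in 41.2% and 56.2% of knockout ones. The matching shares in B cell-like cells were 0.969%, 0.531%, 0.656% and 0.866%, at median depths of 3396 to 3832 UMIs against 13391 to 16792 UMIs in alveolar macrophage-like cells. Over all kept cells of a library, Lmna had a log2 fold change of -2.17 ± 0.18 (adjusted p = 0.0357), a value that mixes expression with the share of alveolar macrophage-like cells. The labels do not say which part of the gene is floxed, so 3-prime counts outside the deleted part would remain after deletion and the residual counts do not measure its efficiency.

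**Figure D1:**
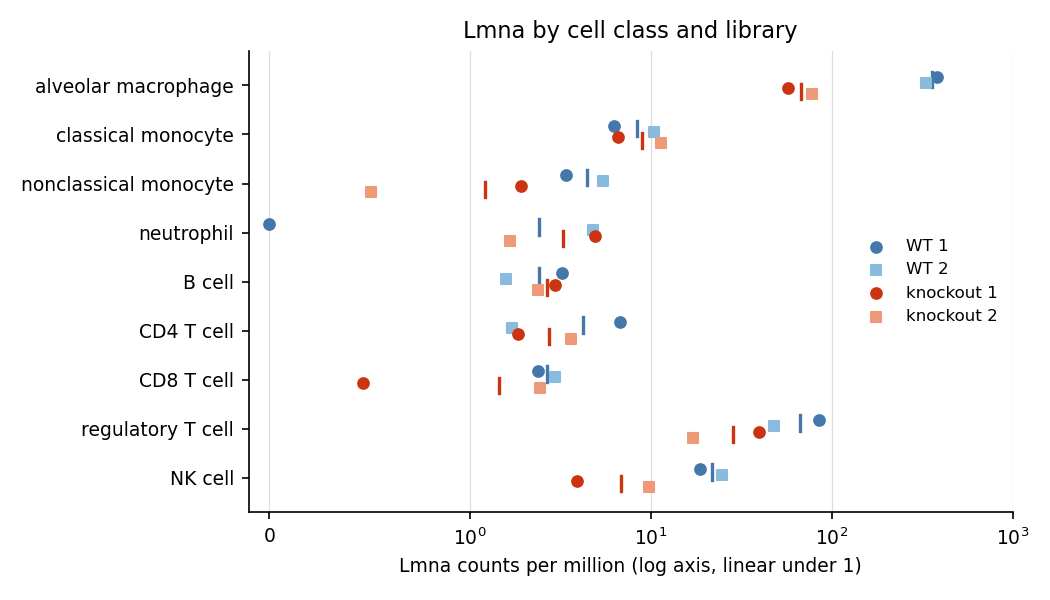
Lmna CPM (x axis, logarithmic, linear under 1) in each of the 9 tested classes; each point is a library (2 WT in blue, 2 knockout in red) and short bars are group means. In alveolar macrophage-like cells the WT libraries lie at 385 and 334 and the knockout libraries at 57.1 and 77.7.

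The second comparison asked whether the makeup of the CD45+ cells differed. Alveolar macrophage-like cells, the resident macrophages of the airspace, made up 6.01% ± 0.232 of WT cells and 1.16% ± 0.338 of knockout cells (mean ± SD, n = 2 libraries each), which is 5.17-fold lower. There were 223 and 232 such cells in the WT libraries and 51 and 32 in the knockout libraries. Mature migratory dendritic cell-like cells rose from 0.119% ± 0.0174 to 0.532% ± 0.0176. Regulatory T cell-like cells rose from 1.75% ± 0.373 to 3.40% ± 0.185. Epithelial cell-like cells, which a CD45 sort should remove, rose from 0.172% ± 0.0578 to 0.528% ± 0.260.

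By the edgeR test on cell numbers over 14 classes, the alveolar macrophage-like share had a log2 fold change of -2.37 ± 0.30 (adjusted p = 1.4e-07). The exact binomial 95% intervals were 5.12% to 6.63% in WT 1, 5.42% to 6.99% in WT 2, 1.04% to 1.83% in knockout 1 and 0.628% to 1.29% in knockout 2. The log2 fold changes were 2.13 ± 0.55 for migratory dendritic cell-like cells (adjusted p = 0.0038), 0.95 ± 0.29 for regulatory T cell-like cells (adjusted p = 0.0116) and 1.61 ± 0.51 for epithelial cell-like cells (adjusted p = 0.0128). The migratory dendritic cell-like and epithelial cell-like shares rested on 4 to 26 cells a library. Plasmacytoid dendritic cell-like cells were at 0.660% ± 0.00700 and 0.321% ± 0.0488 (log2 fold change -1.03 ± 0.44, adjusted p = 0.0712). The 9 remaining classes, which include B cell-like, CD4 and CD8 T cell-like, NK cell-like, monocyte-like and neutrophil-like cells, had adjusted p values of 0.422 to 0.997. An exact permutation test of 2 against 2 libraries cannot go below 0.333, and gave that value for each of the 4 changed classes (two-sided). Under a stricter cell filter the alveolar macrophage-like fall was -2.01 on the log2 scale with an adjusted p of 0.0521, and the regulatory T cell-like rise had one of 0.0664; the migratory dendritic cell-like and epithelial cell-like shares had too few cells and were not tested there. With cells classed by their own markers only the alveolar macrophage-like share passed, and without T cell precursor clusters the epithelial cell-like share had an adjusted p of 0.126. With TMM scaling of the class counts, the epithelial cell-like share had one of 0.224 and the plasmacytoid dendritic cell-like share one of 0.0286. Without WT 2, knockout 1 or knockout 2, only the alveolar macrophage-like share passed among the shares tested, with adjusted p values of up to 0.0023, and without either knockout library the migratory dendritic cell-like and epithelial cell-like shares were not tested. Without WT 1 there were 3 classes past the threshold.

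**Figure D2:**
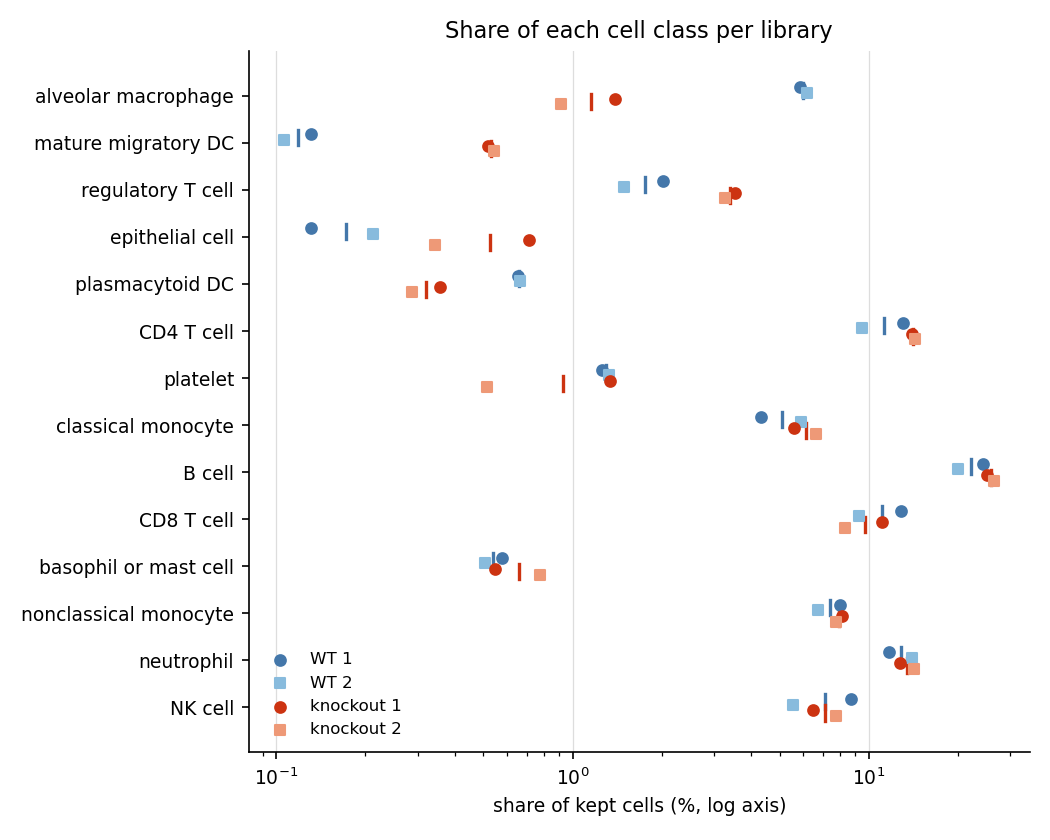
Share of kept cells (x axis, percent, logarithmic) for the 14 tested classes; each point is a library and short bars are group means. Alveolar macrophage-like cells lie at 5.84% and 6.17% in WT and at 1.395% and 0.917% in knockout libraries.

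The main comparison was gene expression in alveolar macrophage-like cells. Several genes of lysosomes and of the p53 response rose in knockout cells (9 of 29 and 7 of 25 listed and measured), and among the genes that rose were the protease gene Ctsk (cathepsin K; 284 ± 5.75 to 1295 ± 53.5 CPM), the late endosome tetraspanin gene Cd63 (141 ± 7.94 to 632 ± 0.95 CPM) and the cell cycle inhibitor gene Cdkn1a (p21; 395 ± 16.1 to 904 ± 25.3 CPM). AA467197 had the highest fold change. It rose 68.0-fold, from 4.29 ± 0.390 to 295 ± 21.3 CPM (mean ± SD, n = 2 libraries each). The immediate early genes Fosb and Nr4a1 fell, as did Nfkbiz, which encodes a nuclear IkB protein (162 ± 21.4 to 45.7 ± 2.79 CPM). Of 9035 genes tested, 275 were higher and 222 lower in knockout cells at an adjusted p under 0.05.

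AA467197 (ENSMUSG00000033213, protein coding, chromosome 2, 122636986 to 122641191, plus strand) had a log2 fold change of 6.09 ± 0.21 (adjusted p = 6.5e-16). Cdkn1a (ENSMUSG00000023067, protein coding, chromosome 17, 29090976 to 29100727, plus strand) had one of 1.20 ± 0.12 (adjusted p = 9.5e-07). For Ctsk (ENSMUSG00000028111, chromosome 3, 95499256 to 95509362, plus strand) it was 2.19 ± 0.13 (adjusted p = 2.8e-11), and for Cd63 (ENSMUSG00000025351, chromosome 10, 128900989 to 128912822, plus strand) 2.17 ± 0.13 (adjusted p = 8.4e-11). Phlda3 (ENSMUSG00000041801, chromosome 1, 135766119 to 135769136, plus strand), a p53 target that restrains Akt, rose by 2.28 ± 0.18 on the log2 scale (adjusted p = 5.8e-09). The other genes with the highest fold changes were Anpep (aminopeptidase N; log2 fold change 3.63), Plpp3, Fkbp11, Ptgs1 (a prostaglandin synthase), Mfge8 (a bridging protein in the uptake of dying cells), Tmem140, Slc44a1 (a choline transporter), Zranb3, Wfdc17 and the chemokine gene Ccl17 (log2 fold change 2.25). In WT cells Anpep, Plpp3, Fkbp11, Ptgs1, Mfge8, Tmem140, Slc44a1 and Zranb3 were all under 8 CPM. Some of the higher genes are also among the 10 leading genes of clusters outside this class: AA467197 in an unnamed cluster led by C1qa, and Ccl17 in mature migratory dendritic cell-like cells, whose share rose 4.38-fold.

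Among the genes with the lowest fold changes, Cpne5 (ENSMUSG00000024008, chromosome 17, 29155556 to 29238167, minus strand), a calcium-dependent membrane-binding protein gene, fell from 219 ± 11.9 to 30.2 ± 2.31 CPM (log2 fold change -2.85 ± 0.21, adjusted p = 2.0e-09). Nfkbiz (ENSMUSG00000035356, chromosome 16, 55811375 to 55838899, minus strand) had a log2 fold change of -1.82 ± 0.20 (adjusted p = 2.4e-06). Others were Apoc1, Mzb1, Lmna, Ccr2, Clec1b, Adgrl3, Sema6d, Batf3, Rasgrp4, Tcf4 and H2-Aa. Apoc1, an apolipoprotein gene, had 3 UMIs in the knockout libraries together, against 254 in WT, a ratio of 15.03 with a counting interval of 5.09 to 73.4. Mzb1 had 2 UMIs against 148, a ratio of 13.1 with an interval of 3.57 to 109.5. Several of these genes mark other cell types: Mzb1 plasma cells, Tcf4 plasmacytoid dendritic cells, Batf3 conventional dendritic cells, Ccr2 monocytes and H2-Aa antigen-presenting cells. In the same cells the B cell transcript Igkc was at 744 ± 752 CPM in WT and 79.7 ± 70.1 CPM in knockout libraries (adjusted p = 0.506).

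**Figure D3:**
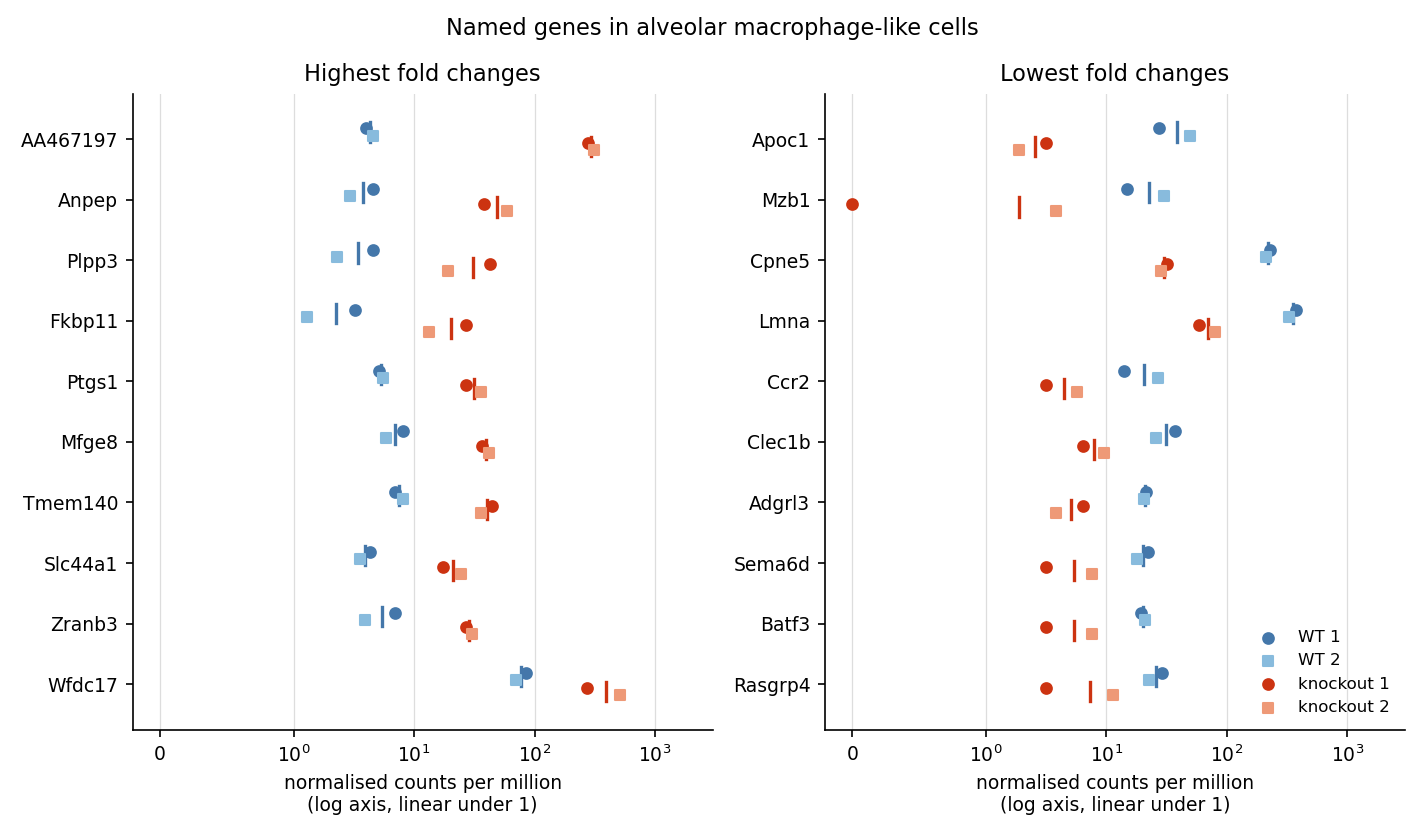
Normalised CPM (x axis, logarithmic, linear under 1) of the 10 named genes with the highest and the 10 with the lowest fold changes in alveolar macrophage-like cells; each point is a library and short bars are group means. Both knockout libraries lie on the same side of both WT libraries for each gene, as the naming rule required; AA467197 goes from 4.29 to 295.

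Of 28 gene lists fixed beforehand, 4 rose in alveolar macrophage-like cells by camera: p53 targets, lysosome, glycolysis and nuclear-encoded oxidative phosphorylation. These calls were made with a preset correlation of 0.01 between genes, and each list had an adjusted p = 0.687 with an estimated correlation. That setting also uses the few residual degrees of freedom of 4 libraries. For p53 targets the estimate was -0.0285, below the preset value, yet the camera p rose from 3.1e-04 to 0.0566. For that list, losing the call therefore does not by itself show that correlation between genes made it. Glycolysis also had an estimate below the preset value (-0.0494). The other called lists, risen or fallen, had estimates above it, from 0.0748 (lysosome) to 0.220 (G1/S cell cycle). For these the preset value was lower than the correlation estimated here, so correlation between genes may have made their calls. Of 25 measured p53 targets, 7 rose, with a median log2 fold change of 0.41 (adjusted p = 0.0043). Adjusted over the list alone, 8 rose and 1 fell. Besides Phlda3 and Cdkn1a they were Ccng1 (86.3 to 176 CPM), the pro-apoptotic gene Bax (164 to 274 CPM), Ei24, Mdm2, the ubiquitin ligase gene that restrains p53 (55.4 to 102 CPM), and Zmat3. Of 29 lysosomal genes, 9 rose (median 0.27, adjusted p = 0.0043); adjusted over the list alone, 12 rose and 1 fell. Cathepsin D (Ctsd) went from 3339 to 6119 CPM, cathepsin L (Ctsl) from 282 to 489 CPM and the saposin precursor Psap from 2804 to 4398 CPM. Glycolytic genes rose in 4 of 14 (Pgam1, Pkm, Ldha and Eno1; 5 adjusted over the list alone; list adjusted p = 0.0488). Nuclear oxidative phosphorylation genes rose in 2 of 26 (Cox5a and Ndufb9; median 0.20, adjusted p = 0.0204); adjusted over the list alone, 4 rose and 1 fell.

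The other 4 called lists fell with the preset correlation, and each also had an adjusted p = 0.687 with an estimated one. Of 18 immediate early genes, which respond to stimulation and also to tissue dissociation, 7 fell and 2 rose (median -0.50, adjusted p = 0.0134); adjusted over the list alone, 9 fell and 2 rose. Nr4a1 went from 299 to 116 CPM, Fosb from 566 to 242 CPM and Dusp1 from 969 to 599 CPM, while Ier3 rose from 70.8 to 170 CPM and Socs3 from 22.96 to 54.9 CPM. In the cholesterol synthesis list (21 measured, median -0.54, adjusted p = 0.0073) 3 genes fell adjusted over the list alone. The 18 measured genes of the G1/S cell cycle list had negative fold changes (median -0.45, adjusted p = 0.0128), and the smallest adjusted p of a member over all genes was 0.0762 (Mcm7, 24.5 and 11.1 CPM). In the G2/M cell cycle list (13 measured, median -0.86, adjusted p = 0.0073) 2 genes fell adjusted over the list alone. Over all genes the smallest adjusted p was that of Anln, at 22.6 and 8.88 CPM (0.0511). Mki67, a marker of dividing cells, was at 20.8 ± 13.9 and 15.2 ± 5.42 CPM (adjusted p = 0.875).

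By fry, only the p53 targets passed of these 8 lists (adjusted p = 0.0288). With the replicate number as a block, glycolysis did not pass by camera (adjusted p = 0.0605). The G2/M list had a positive median of 0.17 without WT 2, and the G1/S list had an adjusted p of 0.265 without WT 2 and 0.183 without knockout 1. Glycolysis did not pass with any library left out (0.0502 to 0.190) or with the length correction (0.126), and nuclear oxidative phosphorylation did not pass without WT 1 (0.276), knockout 1 (0.0868) or knockout 2 (0.0880) or with the length correction (0.127). The lysosome list had an adjusted p of 0.0787 without knockout 1, the immediate early list 0.0606 without knockout 1 and 0.190 without knockout 2, and the cholesterol synthesis list 0.190 without knockout 2.

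**Figure D4:**
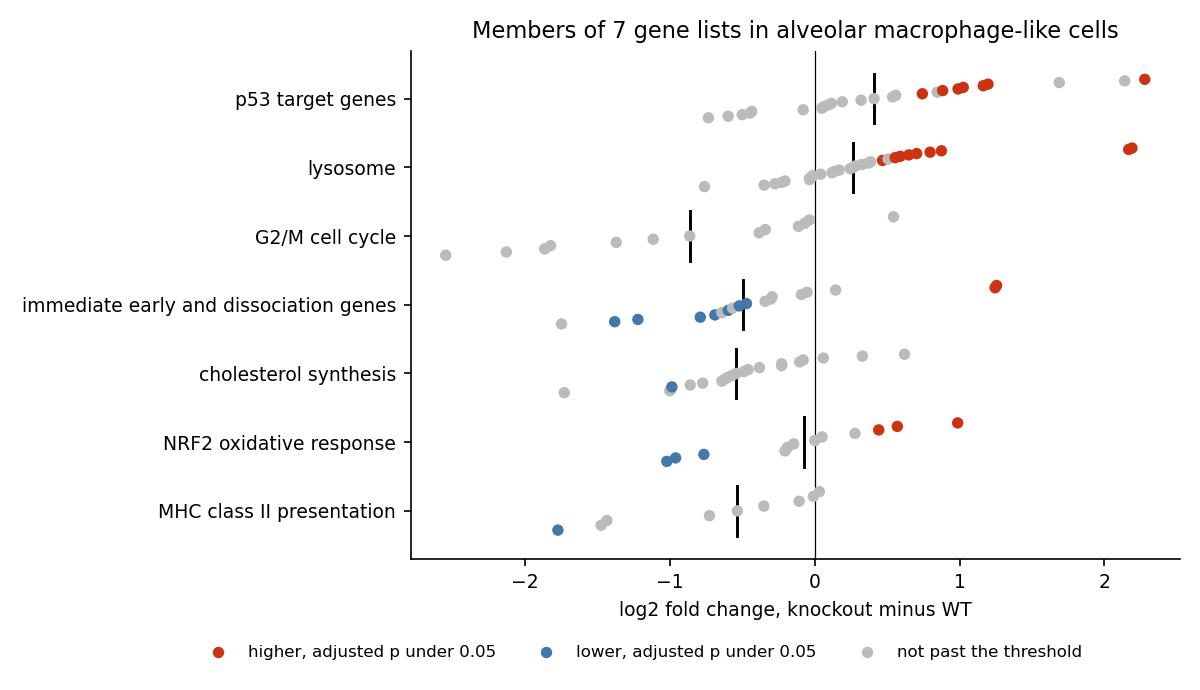
Log2 fold change, knockout minus WT (x axis), of the measured members of 7 gene lists in alveolar macrophage-like cells; each point is a gene, coloured by whether it passed an adjusted p of 0.05, and black bars are list medians. The p53 target and lysosome points past the threshold lie to the right of 0, with medians of 0.41 and 0.27; NRF2 and MHC class II lists are drawn beside the called lists and did not pass.

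Lists that did not pass held single changed genes of note. Of the 12 NRF2 oxidative response genes, the ferritin genes Fth1 (14536 to 21576 CPM) and Ftl1 and the glutathione reductase gene Gsr rose, while heme oxygenase Hmox1 (183 to 90.4 CPM), the cystine transporter gene Slc7a11 and G6pdx fell (list adjusted p = 0.722). In the list of alveolar macrophage regulators, the phagocytic receptor gene Mertk (249 to 155 CPM), Egr2 (239 to 152 CPM) and Pparg, a transcription factor needed for alveolar macrophage identity (144 to 93.8 CPM), fell; the list had an adjusted p of 0.109. In lipid and surfactant handling, Car4 and Npc2 rose and Cd36 and Pparg fell (adjusted p = 0.831). Syne2, a nuclear envelope spectrin, fell from 86.5 to 35.1 CPM, and the other lamin genes gave adjusted p values of 0.866 (Lmnb1, 25.7 ± 4.54 and 23.8 ± 6.68 CPM) and 0.336 (Lmnb2, 38 and 2 UMIs). The monocyte-derived macrophage list (adjusted p = 0.674) held a rise of Gpnmb (239 to 508 CPM) and the fall of Ccr2. Mmp12, a macrophage elastase gene of the senescence list, was at 8.05 ± 6.78 and 391 ± 111 CPM without passing (adjusted p = 0.0711), and was among the leading genes of an interstitial macrophage-like cluster at resolution 2. The ESCRT membrane repair list (adjusted p = 0.275) held a rise of Chmp2b, the heat shock list (adjusted p = 0.427) a rise of Hspe1 and the integrated stress response list (adjusted p = 0.760) a rise of Nupr1.

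NF-kB inflammatory genes had an adjusted p of 0.108, with Nfkbiz, Cxcl2, Ccl2 and Tnfaip3 lower and Ier3 higher. Type I interferon-stimulated genes had an adjusted p of 0.583, with Isg15 higher (2.51 to 11.1 CPM), and interferon gamma-induced genes one of 0.674. The DNA damage response list had an adjusted p of 0.412, cytosolic DNA sensing one of 0.571 and MHC class I presentation one of 0.412. MHC class II presentation had an adjusted p of 0.129, with H2-Aa lower, and passed by camera with the replicate number as a block (adjusted p = 0.0263). The adjusted p was 0.464 for nuclear envelope and lamina partners, 0.682 for senescence genes, 0.497 for apoptosis regulators, 0.427 for actin and SRF targets, 0.674 for ribosomal proteins and 0.412 for mitochondrially encoded oxidative phosphorylation. In these last lists Rps2 rose, and Rpl41, Rpl37, Rps27, mt-Nd3 and mt-Nd4l fell. Rps27, mt-Nd3 and mt-Nd4l have annotated transcripts under 400 nt, and abundant genes of that length had a median log2 fold change of -0.89 in alveolar macrophage-like cells.

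The count of changed genes depended on the tool and on cell number. DESeq2 gave no adjusted p for 5605 of the 9035 genes, and these counted as not called. DESeq2 called 214, of which 204 were among the 497 called by edgeR and changed the same way; with the same 32 cells from each library 159 were called; without a filter on low counts more genes were lower (436) than higher (305); the fit without knockout 1 called 237 and the fit without WT 1 called 278. H2-Aa turned to a log2 fold change of 0.34 when cells called doublets were kept.

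The third comparison asked which knockout effects in alveolar macrophage-like cells differed from those in other immune cells. Slc44a1 and Tmem140 rose more in alveolar macrophage-like cells than in the mean of the 8 other classes, by 2.84 ± 0.52 and 2.18 ± 0.40 on the log2 scale (adjusted p = 2.5e-04 for each). Nfkbiz fell more there (difference -1.84 ± 0.20, adjusted p = 3.8e-09), as did Tcf4 (-1.66 ± 0.48, adjusted p = 0.0329) and Lmna (-1.61 ± 0.43, adjusted p = 0.0302). Ccr2 (-2.69 ± 0.88, adjusted p = 0.0975) and H2-Aa (-2.40 ± 1.13, adjusted p = 0.291) did not pass. The remaining 21 of the 28 genes with the highest or lowest fold changes, AA467197, Ctsk, Cd63 and Phlda3 among them, and also Cdkn1a, had too few counts in some other class for this test. For Lmna the reference held classes with few counts, such as B cell-like cells (2.41 and 2.67 CPM), where a fall could hardly be seen. In NK cell-like and regulatory T cell-like cells its log2 fold changes were -1.57 and -1.35. The Lmna difference therefore does not show a weaker loss in other classes.

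Of 6447 genes with counts in every class, 185 had a knockout effect above and 121 an effect below the mean of the other classes. Of the 320 genes called in alveolar macrophage-like cells and tested here, 172 differed in the same direction. Of the 28 lists, 7 differed by camera. Nuclear oxidative phosphorylation (adjusted p = 0.0048), glycolysis (0.0087) and lysosome (0.0162) were shifted upward. Immediate early genes (adjusted p = 1.2e-05), MHC class II presentation (0.0066), NF-kB inflammatory genes (0.0078) and monocyte-derived macrophage genes (0.0078) were shifted downward. The last of these rested on 3 measured genes, none of them past the threshold over all genes, while 12 were measured in alveolar macrophage-like cells alone, where the median was 0.23. In MHC class II presentation 0 of 6 measured genes passed, with a median difference of -1.79. In alveolar macrophage-like cells alone neither that list (median -0.54, camera adjusted p = 0.129) nor the NF-kB list (median -0.25, 0.108) passed. A difference can also come from changes in the other classes. With an estimated correlation no list passed; for these 7 the adjusted p was 0.0723 for immediate early genes and for monocyte-derived macrophage genes, 0.146 for nuclear oxidative phosphorylation, 0.226 for lysosome and 0.276 for the remaining 3. Against the other myeloid classes alone 138 genes differed, and the fit without knockout 1 gave 75, that without WT 1 gave 146 and that without knockout 2 gave 158.

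The same genotype comparison was made in the 8 other classes with at least 25 cells in every library. Commd10 (ENSMUSG00000042705, protein coding, chromosome 18, 46958816 to 47234284, plus strand), a subunit of an endosomal sorting complex, rose in 6 of them. In classical monocyte-like cells it went from 12.0 ± 2.98 to 88.9 ± 4.28 CPM (log2 fold change 2.86 ± 0.20, adjusted p = 4.0e-06) and in nonclassical monocyte-like cells from 14.3 ± 2.19 to 77.9 ± 5.03 CPM (2.43 ± 0.19, adjusted p = 4.1e-07). In neutrophil-like cells there were 3 UMIs in WT and 135 in knockout libraries, a ratio of 47.3 with a counting interval of 15.8 to 232 (adjusted p = 3.1e-04). In regulatory T cell-like cells there were 2 and 48, a ratio of 14.2 with an interval of 3.74 to 121.0 (adjusted p = 0.0147). Commd10 rose by 1.49 ± 0.25 in B cell-like cells (adjusted p = 0.0129) and by 0.98 ± 0.24 in NK cell-like cells (adjusted p = 0.0270). It did not pass in CD4 T cell-like (1.11 ± 0.27, adjusted p = 0.0529), CD8 T cell-like (0.87 ± 0.25, adjusted p = 0.293) or alveolar macrophage-like cells (0.63 ± 0.30, adjusted p = 0.251).

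**Figure D5:**
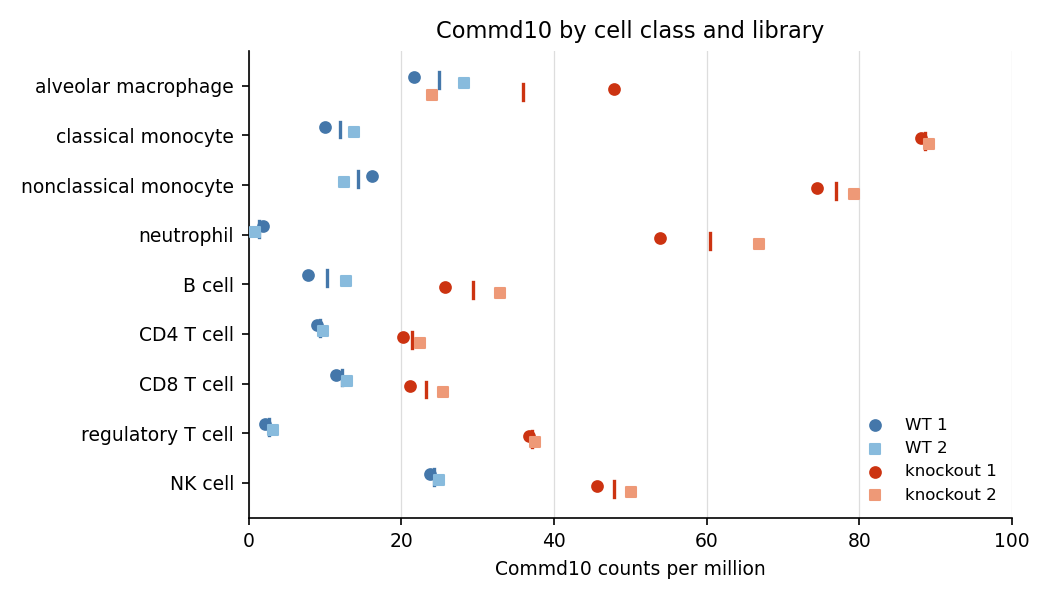
Commd10 CPM (x axis) in the 9 tested classes; each point is a library and short bars are group means. Both knockout libraries lie above both WT libraries in 8 of the 9 classes; in alveolar macrophage-like cells WT 2 (28.2) lies above knockout 2 (24.1).

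Other genes were called in some classes, each by a test within the class and not by a test between classes. Socs3, a feedback inhibitor of cytokine signalling, rose in classical monocyte-like (40.7 to 147 CPM) and nonclassical monocyte-like cells (139 to 255 CPM). Ramp1, a subunit of the receptor for the neuropeptide CGRP, fell in 4 of the 8 classes where it was tested: in neutrophil-like (42.1 to 4.51 CPM; log2 fold change -3.18 ± 0.36, adjusted p = 0.0029) and nonclassical monocyte-like cells (46.1 to 9.01 CPM; -2.35 ± 0.24, adjusted p = 1.3e-05), in classical monocyte-like (104 to 47.4 CPM; -1.13 ± 0.16, adjusted p = 0.0048) and alveolar macrophage-like cells (237 to 111 CPM; -1.10 ± 0.16, adjusted p = 1.5e-04), and rose in CD8 T cell-like cells (130 to 201 CPM; 0.64 ± 0.13, adjusted p = 0.0267). With cells classed by their own markers Ramp1 was at -0.17 in CD8 T cell-like cells, where edgeR called 0 genes, with 295 at an unadjusted p under 0.05. Regulatory T cell-like cells gained the chemokine Cxcl10 (14.4 to 103 CPM) and the costimulatory receptor Tnfrsf4 (70.9 to 192 CPM). With cells classed by their own markers edgeR called 1 gene in this class, outside the 23 called here, and with the replicate number as a block it called 0 (394 and 419 genes at an unadjusted p under 0.05). NK cell-like cells gained the receptor gene Klra1 (104 to 192 CPM) and Camk2b (2.22 ± 1.35 to 29.3 ± 18.4 CPM, a wide spread between the knockout libraries) and lost Styk1 (189 to 72.4 CPM). Fyb, an adaptor in T cell activation, rose in CD4 T cell-like (532 to 808 CPM) and CD8 T cell-like cells (426 to 647 CPM), and Igfbp4 rose in CD4 T cell-like cells (476 to 688 CPM). Borcs5 rose in neutrophil-like cells (4.37 to 31.3 CPM). Sva had 0 UMIs in WT B cell-like cells and 43 in knockout ones, at least 13.8-fold higher against a floor of 3 counts over the group (adjusted p = 0.0035).

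Of the lower genes, those with transcripts under 600 nt numbered 18 of 34 in classical monocyte-like, 17 of 45 in nonclassical monocyte-like, 2 of 4 in neutrophil-like, 17 of 32 in B cell-like, 22 of 50 in CD4 T cell-like, 19 of 37 in CD8 T cell-like, 13 of 19 in regulatory T cell-like and 25 of 57 in NK cell-like cells. The smallest p values belonged to Rps28 in B cell-like (4078 to 1616 CPM) and regulatory T cell-like cells (3699 to 1342 CPM), Rpl38 in CD8 T cell-like cells (4807 to 2062 CPM), Bola2 and Rps21 in CD4 T cell-like cells, Rps29 in neutrophil-like, NK cell-like and regulatory T cell-like cells, mt-Atp8 and the histone gene Hist1h2ap in classical monocyte-like cells and Eps8l1 in B cell-like cells (24.3 to 2.44 CPM). In CD8 T cell-like cells Rps28 also fell (6250 to 2480 CPM). Over the 9 classes, the median of class medians was -0.91 for non-ribosomal genes with transcripts under 400 nt and at least 100 CPM. Only 4 to 9 genes a class were of this kind, mitochondrial ones included. Genes under 600 nt, without ribosomal and mitochondrial ones (257 to 403 a class), had class medians of -0.09 to 0.07, so they did not fall as a set. A set so much larger says little about the abundant short transcripts. Among the called lower genes, those under 600 nt were over-represented in each class. By Fisher's exact test p ran from 1.8e-19 in NK cell-like to 0.0143 in neutrophil-like cells.

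The edgeR counts of higher and lower genes were 6 and 34 in classical monocyte-like, 9 and 45 in nonclassical monocyte-like, 5 and 4 in neutrophil-like and 2 and 32 in B cell-like cells. They were 5 and 50 in CD4 T cell-like, 2 and 37 in CD8 T cell-like, 4 and 19 in regulatory T cell-like and 16 and 57 in NK cell-like cells. These counts moved by over 1.5 times with many settings, and in B cell-like and CD4 T cell-like cells edgeR called 0 genes without WT 1, where 423 and 343 genes had an unadjusted p under 0.05. Differences in count between classes were not tested.

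The last comparison asked whether fewer alveolar macrophage-like cells were cycling. After thinning each cell to 5985 UMIs, at least 3 G2/M genes were detected in 14 of 209 and 12 of 204 WT cells and in 1 of 40 and 1 of 31 knockout cells. The shares were 6.70% and 5.88% in WT and 2.50% and 3.23% in knockout libraries, a difference of -3.43 percentage points against a spread between replicates of 0.546 (SD). The exact binomial 95% intervals were 3.71% to 10.98%, 3.08% to 10.0%, 0.0633% to 13.2% and 0.0816% to 16.7%, so the knockout shares were not resolved from the WT shares at this depth (two-sided exact permutation p = 0.333, the smallest that 2 against 2 allows). The difference was 0.06 points when doublets were kept and 0.56 points under the stricter cell filter, and such counts also pick up free RNA.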

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

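The tests in this part were chosen after the results were seen, except the test of the class difference itself and, for residual Lmna, that of a few cells with an intact gene and, for Commd10, that of its neighbouring genes.

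The knockout effect in alveolar macrophage-like cells differed from the mean of the other classes for 306 genes and for 7 gene lists, by the test of the difference itself, with 0 of the lists past the threshold in camera with an estimated correlation. Ramp1 had a log2 fold change of -3.18 in neutrophil-like cells and 0.64 in CD8 T cell-like cells, with both knockout libraries below both WT libraries in the former and above them in the latter. It fell in 4 of the 8 classes tested; the difference between neutrophil-like and CD8 T cell-like cells was not tested, and with cells classed by their own markers the CD8 T cell-like value was -0.17. T cell precursor cells, led by Rag1 and Dntt, numbered 450 in WT 2, 11.97% of its cells, against 0 in WT 1, 0 in knockout 1 (which allows up to 0.0821%) and 10 in knockout 2. They were in no expression comparison by class but counted in the total of every share, and without them the adjusted p of the epithelial cell-like share went from 0.0128 to 0.126 and that of the plasmacytoid dendritic cell-like share from 0.0712 to 0.0314. An unnamed cluster led by Ier3, Il1rn, Cxcl3 and Cxcl2, with some neutrophil markers, held 18 cells in knockout 1 and 27 in knockout 2, against 0 in WT 1 and 2 in WT 2; of all its cells, 44.0% had been called doublets before the rest were counted.

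Abundant short transcripts were lower in the knockout libraries in every tested class. Genes with transcripts under 400 nt and at least 100 CPM had median log2 fold changes from -1.02 to -0.21 over the 9 classes when ribosomal protein genes were left out, which left 4 to 9 genes a class, mitochondrial ones included. The bound of 400 nt was set after medians under 600 nt, without ribosomal and mitochondrial genes, had come out between -0.09 and 0.07. A fall of ribosomal protein genes as a class is argued against by those with transcripts of at least 800 nt, whose median over classes was 0.0498. A library step that recovers short transcripts less well stays open, since the highest of the non-ribosomal medians, -0.21 from 4 genes in neutrophil-like cells, only restates the pattern from which the bound came. Such a step and the genotype cannot be told apart, because the labels give no library batch; the WT libraries differed from each other by -0.18 and the knockout libraries by 0.37 to 0.51 in these transcripts.

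Lmna UMIs were left in knockout alveolar macrophage-like cells, 37 in knockout 1 and 42 in knockout 2. Free RNA from other cells is argued against as the source, since the Lmna level was at least 19.3 times that in B cell-like cells of the same library. Whether a few cells that kept an intact gene account for them in part stays open. The top 10% of cells held 54.1% of the UMIs in knockout 1 and 50% in knockout 2. The dispersion index lay above the range of counting noise in knockout 2 (3.23 against 0.571 to 1.599) and within it in knockout 1 (1.25 against 0.605 to 1.63). In WT cells, which carry no Cre, the index was also above that range. It was 2.19 against 0.819 to 1.2 in WT 1 and 1.98 against 0.821 to 1.206 in WT 2. WT cells held more Lmna UMIs per cell (1403 in 223 cells of WT 1, 1016 in 232 cells of WT 2), and ordinary spread raises this index more at higher counts. The WT values therefore do not show what index ordinary spread would give in knockout cells. The 2 knockout libraries differed and did not settle the question. A floxed part that leaves the 3-prime end in place also stays open and was not tested.

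Commd10 was higher in knockout libraries of most classes, whatever their Lmna level. A change of Commd10's size is argued against in neighbouring genes on the side tested. Of 48 pairs of a class and 1 of 6 genes within 500 kb, 0 passed by edgeR (smallest adjusted p = 0.102). In neutrophil-like cells Ap3s1, the nearest of them, was at 0.11 ± 0.19 against 5.42 ± 0.45 for Commd10. But Ap3s1 was positive in all 9 classes (0.11 to 0.50), so a smaller shared rise stays open. All 6 genes lie before the start of Commd10, and genes beyond its end were not tested. A response to the loss of Lmna transcript in the same cell is argued against by the classes with under 10 CPM of Lmna in WT, whose lowest Commd10 log2 fold change was 0.87, against 0.63 in alveolar macrophage-like cells; in 4 of these 6 classes it lay above by more than both standard errors. A candidate explanation is the Cre transgene, since a widely used Vav1 Cre line carries its insertion in Commd10; the labels do not name the line. Both knockout libraries lay above both WT libraries in 8 of 9 classes, but all knockout mice and no WT mice carry Cre, so transgene and genotype cannot be told apart.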

How the results depend on the processing

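The transcript length correction, the 20% mitochondrial limit, the removal of T cell precursors, the first filter of the class difference test and the own marker score for cycling were chosen after the data were seen. Of 189 alternative values of the comparisons, 112 kept their side of the threshold or stayed within the range allowed, 76 moved and 1 lost its call. The Lmna fall in alveolar macrophage-like cells passed under every alternative run, with log2 fold changes of -2.58 to -2.16 when a library was left out. The alveolar macrophage-like share lay between -2.71 and -2.10 then, and was -2.01 (adjusted p = 0.0521, against 1.5e-08 to 0.0102 under the other alternatives) with the stricter cell filter, which left fewer cells. Of 69 named genes past the threshold in alveolar macrophage-like cells, 21 passed under every alternative, among them AA467197, Cdkn1a, Phlda3, Ccng1, Cd63, Ctsk, Ctsd, Gpnmb, Cpne5, Nfkbiz and Hmox1. Of their 1019 alternative values, 843 passed in the same direction, 173 kept the direction without passing and 3 reversed. A gene to which DESeq2 gave no adjusted p counted as not passing there. The knockout libraries held 51 and 32 alveolar macrophage-like cells. The stricter cell filter left under 25 of them, and under 25 of the B cell-like, CD8 T cell-like and regulatory T cell-like cells, in some library and gave no count there. In a leave-out fit with a single library in a group, that library is assumed to vary like the other group.

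Counts of changed genes in alveolar macrophage-like cells (497) were 187 with the replicate block, 214 with DESeq2, 159 with the same number of cells per library and 237 to 514 when a library was left out. In classical monocyte-like cells (40) they were 24 with the block, 160 without the low-count filter and 8 to 175 with a library left out. In nonclassical monocyte-like cells (54) they were 164 with the block, 31 with DESeq2, 151 without the filter and 80 to 185 with a library left out. In neutrophil-like cells (9) they were 68 with the block, 15 with DESeq2, 83 without the filter, 26 with the stricter cell filter, 41 with the own marker score, 35 with that score and the 20% mitochondrial limit, 15 with the length correction and 30 to 92 with a library left out. In B cell-like cells (34) they were 107 without the filter, 84 at resolution 2, 65 with the own marker score and 20% limit, 22 with the length correction and 0 (edgeR, without WT replicate 1, with 423 genes at an unadjusted p under 0.05) to 95 with a library left out. In CD4 T cell-like cells (55) they were 33 with the block, 31 with DESeq2, 104 without the filter, 23 with the stricter cell filter and 0 (edgeR, without WT replicate 1, with 343 genes at an unadjusted p under 0.05) to 107 with a library left out. In CD8 T cell-like cells (39) they were 82 without the filter, 0 by edgeR with the own marker score at either mitochondrial limit (unadjusted p under 0.05 for 295 and 299 genes), and 16 to 51 with a library left out. In regulatory T cell-like cells (23) they were 0 by edgeR with the block (unadjusted p under 0.05 for 419 genes), 70 without the filter, 1 with the own marker score at either limit and 47 to 108 with a library left out. In NK cell-like cells (73) they were 26 with DESeq2, 42 with the own marker score, 45 with that score and the 20% limit, and 57 to 105 with a library left out. The replicate numbers are not stated to pair animals, and the correlations between same-numbered differences, ran from -0.048 to 0.0967 over the 9 classes. The cause of these moves was not tested.

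The genes that differed between classes (306) were 138 against the other myeloid classes, 288 with the first filter, which was close to the main count, and 75 to 229 with a library left out. The number of changed class shares (4) was 0 with the stricter cell filter, 1 with the own marker score at either mitochondrial limit and 1 to 3 with a library left out, but the migratory dendritic cell-like and epithelial cell-like shares had too few cells for a test with the stricter filter and without either knockout library. The number of called lists (8) was 0 with an estimated correlation, 1 by fry and 3 to 7 with a library left out. The cycling difference (-3.43 points) was 0.055 with doublets kept, 0.56 with the stricter filter, -10.8 without thinning, -1.25 with the own marker score and -3.84 to -3.02 with a library left out; the cause was not tested. Reversals were few, and their cause was not tested. Lmnb1 was 0.065 with the own marker score, 0.27 with the 20% limit added and 0.26 with the same number of cells, 0.05 without WT replicate 1 and 0.13 without knockout replicate 1, within a range of -0.43 to 0.13 when a library was left out. Mki67 was 0.39 with the own marker score and 20% limit and lay between -0.99 and 0.48 with a library left out, the highest without WT replicate 2. The median of the G2/M list lay between -2.44 and 0.17 then, with the same library giving the highest. With doublets kept, own marker score, and that score with the 20% limit, H2-Aa was 0.34, 0.13 and 0.12, H2-Eb1 1.57, 0.43 and 0.38, and H2-Ab1 0.91, 0.41 and 0.36. Irf3 was 0.02 with the same number of cells, and Ramp1 in CD8 T cell-like cells was -0.17 with the own marker score at either limit.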

Other observations

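The observations here were made after the results were seen, apart from the list tests in each class, which were planned. Camera with an estimated correlation uses the few residual degrees of freedom within a class. No pathway list passed with it in any class, so it could not tell these lists apart. By fry, 0 pathway lists passed in each of the 8 classes other than alveolar macrophage-like cells. The pathway calls below therefore rest on camera with the preset correlation alone.

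All 28 measured type I interferon-stimulated genes had positive fold changes in neutrophil-like cells (median log2 fold change 0.86, camera adjusted p = 2.0e-14), and 2 passed over all genes, Slfn5 (log2 fold change 1.54) and Ifi27l2a (1.45); adjusted over the list alone, 10 rose. The list had an adjusted p of 0.770 with an estimated correlation and 0.563 by fry. A neutrophil-like cluster led by Rsad2, Slfn4, Isg15 and Ifit1 held 3.81% and 2.10% of the neutrophil-like cells of WT 1 and WT 2, and 6.68% and 6.25% of those of knockout 1 and knockout 2. In B cell-like cells 23 of 25 members were positive (median 0.34, adjusted p = 2.4e-06) and in nonclassical monocyte-like cells 22 of 29 (median 0.26, adjusted p = 0.0032), where Irf7 rose (113 to 169 CPM). In these 2 classes the adjusted p with an estimated correlation was 0.746 and 0.770.

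MHC class I genes had higher values in several lymphoid and myeloid classes. In B cell-like cells 13 of 14 were positive (median 0.30, adjusted p = 2.5e-04; 7 rose adjusted over the list alone), in neutrophil-like cells 12 of 14 (median 0.48, adjusted p = 1.9e-04; 4 rose), in NK cell-like cells 11 of 14 (median 0.24, adjusted p = 0.0067; 5 rose) and in classical monocyte-like cells 12 of 14 (median 0.18, adjusted p = 0.0129; 3 rose). With an estimated correlation these had adjusted p values of 0.746, 0.700, 0.695 and 0.823. In NK cell-like cells G1/S genes (median -0.43, adjusted p = 1.3e-05) and cholesterol synthesis genes (median -0.50, adjusted p = 3.6e-05) were lower, and each had an adjusted p = 0.695 with an estimated correlation. Immediate early genes were higher in NK cell-like cells (median 0.28, adjusted p = 7.7e-04) and nonclassical monocyte-like cells (median 0.27, adjusted p = 0.0032), with adjusted p values of 0.695 and 0.659 with an estimated correlation. The list of mitochondrially encoded oxidative phosphorylation genes was shifted upward in neutrophil-like cells (median 0.74, camera adjusted p = 2.4e-05, and 0.770 with an estimated correlation). Mitochondrial counts were only 0.25% to 0.37% of a median neutrophil-like cell, and free RNA was not subtracted, so this shift rests on low values. The same genes were lower in 7 other classes: classical monocyte-like (adjusted p = 0.0135), nonclassical monocyte-like (0.0239), B cell-like (0.0143), CD4 T cell-like (5.7e-04), CD8 T cell-like (0.0332), regulatory T cell-like (0.0069) and NK cell-like cells (6.8e-04), with 0.659 to 0.949 with an estimated correlation. Medians there were only -0.24 to -0.06, with 1 to 3 genes called in each class (mt-Nd3, mt-Nd4l and mt-Atp8). All of them are short in the annotation, like those lower in the knockout libraries at large.

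Chil3, an abundant transcript of alveolar macrophages, was lower in knockout B cell-like cells (24.1 to 7.19 CPM, log2 fold change -1.75), CD4 T cell-like cells (19.3 to 6.03 CPM), CD8 T cell-like cells (16.6 to 5.53 CPM) and NK cell-like cells (19.6 to 5.47 CPM), in libraries that held fewer alveolar macrophage-like cells. An unnamed cluster led by the CD8 and NK genes Ccl5, Ctsw, Il2rb and Nkg7 made up 1.89% and 2.00% of WT cells and 4.49% and 2.78% of knockout cells. Another, led by C1qa, C1qb and C1qc and with AA467197 among its top genes, matched interstitial macrophages and conventional dendritic cells in its finer clusters and made up 1.55%, 1.28%, 1.72% and 2.06% of cells in WT 1, WT 2, knockout 1 and knockout 2. At resolution 2 an interstitial macrophage-like cluster was named (21, 11, 34 and 33 cells) and its share rose (log2 fold change 1.15, adjusted p = 0.0229), while with cells classed by their own markers the share was at 0.33 (adjusted p = 0.750).

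Only lists with at least 3 measured genes were tested among those of other cell types. In alveolar macrophage-like cells the B cell free RNA list had an adjusted p of 0.632 and the T and NK cell free RNA list one of 0.879. The list of alveolar epithelial cells was higher in classical monocyte-like cells (3 genes, median log2 fold change 2.20, adjusted p = 8.4e-04; 0.178 with an estimated correlation and 0.130 by fry), and B cell free RNA was higher in neutrophil-like cells (4 genes, median 0.54, adjusted p = 0.0136; 0.254 and 0.0640). Cav1, a gene of endothelial and type 1 alveolar epithelial cells, rose in alveolar macrophage-like cells (38.7 to 103 CPM, log2 fold change 1.39, adjusted p = 7.4e-05), and Sftpc was at 11.1 ± 0.954 and 22.7 ± 10.6 CPM (adjusted p = 0.104).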
